A study of Mus musculus with 8 samples.

How the data were processed

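RNA was prepared from sorted LSK cells of 4 wild type and 4 Jmjd6 KO mice and sequenced as polyA RNA, per the labels' protocols, which also give 1 sample per mouse. The deposited table holds whole-number counts per gene symbol for 26146 genes and 8 libraries, and no row lacks a gene name. Reads were aligned with HISAT2 to the mouse build mm10, per the submitters' processing notes; the aligner's version, the counting tool, its annotation and its strand setting are not given in the sources used here. Counts of overlapping, antisense or near-identical genes may therefore share reads, and gene totals carry no information on exons or splicing, so splicing was not analysed here.

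Each column was matched to a sample by the genotype and replicate number in its name. Total counts ranged from 9344779 to 15079960 per library. Any pair of replicates differed by far more than sampling noise, with a chi-square per degree of freedom from 6.89 to 93.47, so no library was counted as a repeat of another. The common biological coefficient of variation was 27.8%. The counting interval of the Syce1 ratio and the floor of Sva cover counting error only, and the interval of the log2 fold change of Jmjd6 comes from the SE of the edgeR fit, which includes the spread between mice.

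The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, KO against wild type over all 8 libraries with no covariate, TMM scaling and the default filter of filterByExpr (min.count 10, min.total.count 15), which kept 13439 genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. CPM values of genes are counts scaled to the TMM-adjusted library size, and those of Xist as a check of the libraries to the plain total. Log2 CPM used a prior count of 2. A group at 0 was compared through a floor of 3 counts over the group, and a ratio of few counts was given its exact 95% interval. Single values were compared by two-sided exact permutation tests. The scripts were tested on simulated counts for this comparison, drawn with the real means. In the draw with changed genes 13277 genes passed the filter and were tested. Of 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, 11.9%, 44.8% and 93.9% were called. Of 108 calls 8 were of unchanged genes, and 0 genes and 0 lists were called with none changed. The limit of the adjustment loosens as calls increase, so these shares may exceed those of the real comparison, which had 8 calls. The simulated genes were drawn independently of one another, in a single draw per setting. The simulation therefore could not test how list results behave when members are correlated.

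Before the data were examined, 35 gene lists were fixed, and 34 with at least 5 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Each was also tested with camera's estimated correlation, with fry and, as chosen after seeing the data, with permutation of list means. The genes named were also fixed by a rule: Jmjd6 with its chromosome 11 neighbours and the sex-linked genes; every gene past the threshold with a mean log2 CPM above 1, non-overlapping groups and no predicted name, up to 12 per direction and the 5 with the smallest p, of which 7 passed; and up to 4 members per list with the smallest p. Genes named outside this rule, Oasl1 in the report and those in the last part of the text, were chosen after their values were seen. Some genes that the rule names and the result of 1 list are not reported here.

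Alternatives planned beforehand were DESeq2 size factors, library size only, no filter, CPM above 1 in at least 4 libraries, a replicate block, leaving out each library, limma voom with sample weights, the Wald test of DESeq2 1.42.0, robust shrinkage, thresholds of 0.01 and 0.1, a minimum fold change of 1.2, leaving out sex-linked genes, Y-linked expression as a covariate, and 1 surrogate variable from sva 3.50.0. Of these, robust shrinkage, the minimum fold change, leaving out sex-linked genes and both covariates were planned for the count of genes and applied to Jmjd6 itself after seeing the data. Also chosen after seeing the data were the 6 libraries with Y-linked counts, leaving out ribosomal RNA genes, and removing a loess trend of log2 fold change on transcript length and mean log2 CPM. Positions and transcript lengths came from GENCODE M21 and RefSeq GRCm38.p6, the build that mm10 names: 25308 symbols were placed by the former, 568 by the latter, 12 by a synonym, and 258 had no position.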

Results

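Messenger RNA was measured by bulk RNA sequencing in Lin-Sca1+Kit+ (LSK) cells sorted from 8 mice. LSK cells are the bone marrow fraction that holds the haematopoietic stem cells and the earliest multipotent progenitors. In 4 mice a floxed Jmjd6 gene had been deleted in haematopoietic lineages by a Cre recombinase (Jmjd6 KO), and 4 mice were wild type, with 1 library per mouse. Jmjd6 encodes a JmjC-domain oxygenase that hydroxylates lysine residues of proteins, splicing factors among them. Total counts per library were 9344779, 14289574, 10019830 and 15079960 in wild type replicates 1 to 4 and 11380263, 9964528, 13177797 and 13516922 in Jmjd6 KO replicates 1 to 4.

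The libraries differed in ways that did not follow genotype. Wild type replicate 4 and Jmjd6 KO replicate 3 carried Xist, the transcript of the inactive X chromosome, at 1631.4 and 888.2 CPM (counts scaled to the size of the library) and had 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together. The other 6 libraries had between 3660 and 4814 Y-linked counts and Xist at no more than 4.9 CPM, so each genotype held 1 library of this kind. Wild type replicate 1 carried the erythroid transcript Car1 at 339 CPM, against 7.58 to 41.2 CPM in the other 3 wild type libraries, and the granule protease transcript Elane at 785 CPM, against 13.7 to 56 CPM. Jmjd6 KO replicate 3 stood apart on the first principal component, which held 37.8% of the variance, with a score of 83.9 against -28 to 9.4 in the other 7 libraries.

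The first comparison asked whether the targeted gene was reduced in the libraries labelled KO. Jmjd6 fell to 49% of its wild type level in the KO libraries, from 58.6 ± 5.93 to 28.7 ± 1.41 CPM (mean ± SD, n = 4 per group). The log2 fold change was -1.03, with a 95% interval from -1.36 to -0.70 and an adjusted p of 0.0381 by edgeR's quasi-likelihood test. The wild type libraries held 52.5, 63.7, 54.6 and 63.7 CPM and the KO libraries 28.7, 28.1, 30.7 and 27.5 CPM, so the groups did not overlap. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries can give. Jmjd6 lies on the minus strand of chromosome 11 from 116837432 to 116843449 (mm10), and its first 172 bases are shared with Mettl23 on the opposite strand. Mettl23 stood at 78.5 CPM in wild type and 79.4 CPM in KO, with a log2 fold change of 0.02 and an adjusted p of 0.992 by edgeR. The count is a gene total, so reads from exons inside and outside the deleted part were not told apart, and the 28.7 CPM left do not measure how many cells kept an intact gene. With single libraries left out, the log2 fold change stayed between -1.06 and -0.99, and the adjusted p by edgeR rose to as much as 0.254, with the call held only without KO replicate 3. Against a minimum fold change of 1.2 the call was also lost, at an adjusted p of 0.101 by edgeR.

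None of the 15 measured genes around Jmjd6 on chromosome 11 passed edgeR's test over all genes or adjusted over the list alone. Srsf2, a splicing factor gene, and Mfsd11 gave log2 fold changes of 0.01 and 0.16, and the list's median was -0.03 while its mean was -0.35. The mean rested on Sphk1, with a log2 fold change of -4.41 and an adjusted p of 0.518 by edgeR, which reached 38.9 CPM in wild type replicate 1 and no more than 2.26 CPM in the other 3 wild type libraries; without that library Sphk1 gave -1.86. Other members, Unc13d, Evpl, Ube2o, Fbf1, St6galnac2, Srp68, Rnf157, Ten1, Sec14l1 and Exoc7, lay between -0.61 and 0.62. Camera gave the list an adjusted p of 0.299, and 0.705 with an estimated correlation.

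The second comparison asked which genes differed between Jmjd6 KO and wild type LSK cells. Beside Jmjd6, 7 of 13439 tested genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test: Sva, Syce1, Commd10 and Zcwpw1 rose in KO, and H2-Q6, H2-Q7 and Igf2r fell. The largest rises were of genes with almost no reads in wild type, Sva, which encodes a seminal vesicle antigen, and Syce1, which encodes a component of the synaptonemal complex of meiosis. The largest falls were of H2-Q7 and H2-Q6, neighbouring class I histocompatibility genes. In all 8 called genes every KO library lay on one side of every wild type library.

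Sva (chromosome 6, 42038394 to 42042851, plus strand) had 0 counts in all 4 wild type libraries and between 94 and 171 counts in each KO library. Set against a floor of 3 counts over the wild type group, Sva was at least 169.9-fold higher in KO, where it stood at 10.2 ± 2.19 CPM (SD, n = 4; adjusted p = 0.00128 by edgeR). Syce1 (chromosome 7, 140777229 to 140787852, minus strand) had 2 counts in the wild type libraries together and 204 in the KO libraries, a ratio of 108.1 with a 95% counting interval from 29.5 to 898 and an adjusted p of 0.0238 by edgeR. Both wild type counts of Syce1 lay in wild type replicate 2, so the ratio rests on that library, without which the wild type group was at 0 and the adjusted p was 0.0602 by edgeR. Commd10 (chromosome 18, 46958816 to 47234284, plus strand), which encodes a COMM-domain protein, rose from 44.0 ± 3.35 to 94.9 ± 12.3 CPM (log2 fold change 1.11, SE 0.152, adjusted p = 0.0277 by edgeR). Zcwpw1 (chromosome 5, 137787798 to 137822621, plus strand), a histone methylation reader known from meiosis, rose from 15.8 ± 2.9 to 40.6 ± 4.3 CPM (log2 fold change 1.37, SE 0.19, adjusted p = 0.0277 by edgeR).

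H2-Q7 (chromosome 17, 35439155 to 35443773, plus strand) fell from 235 ± 37.7 to 40.3 ± 13.1 CPM, a log2 fold change of -2.54 (SE 0.235, adjusted p = 0.00128 by edgeR). H2-Q6 (chromosome 17, 35424850 to 35430055, plus strand) fell from 157 ± 34.9 to 32.4 ± 14.7 CPM, a log2 fold change of -2.28 (SE 0.299, adjusted p = 0.0238 by edgeR). H2-Q6 and H2-Q7 are near-identical copies, so the split of reads between them is uncertain. Igf2r (chromosome 17, 12682406 to 12769664, minus strand), the receptor that carries IGF2 and mannose 6-phosphate proteins to lysosomes, fell from 20.2 ± 2.44 to 6.89 ± 1.49 CPM (log2 fold change -1.55, SE 0.225, adjusted p = 0.0357 by edgeR). Igf2r shares 28354 bases with the antisense gene Airn, and Zcwpw1 shares 670 bases with the antisense gene Pilra; as the strand setting of the counting is not given in the sources used here, their reads may not have been told apart.

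**Figure D1:**
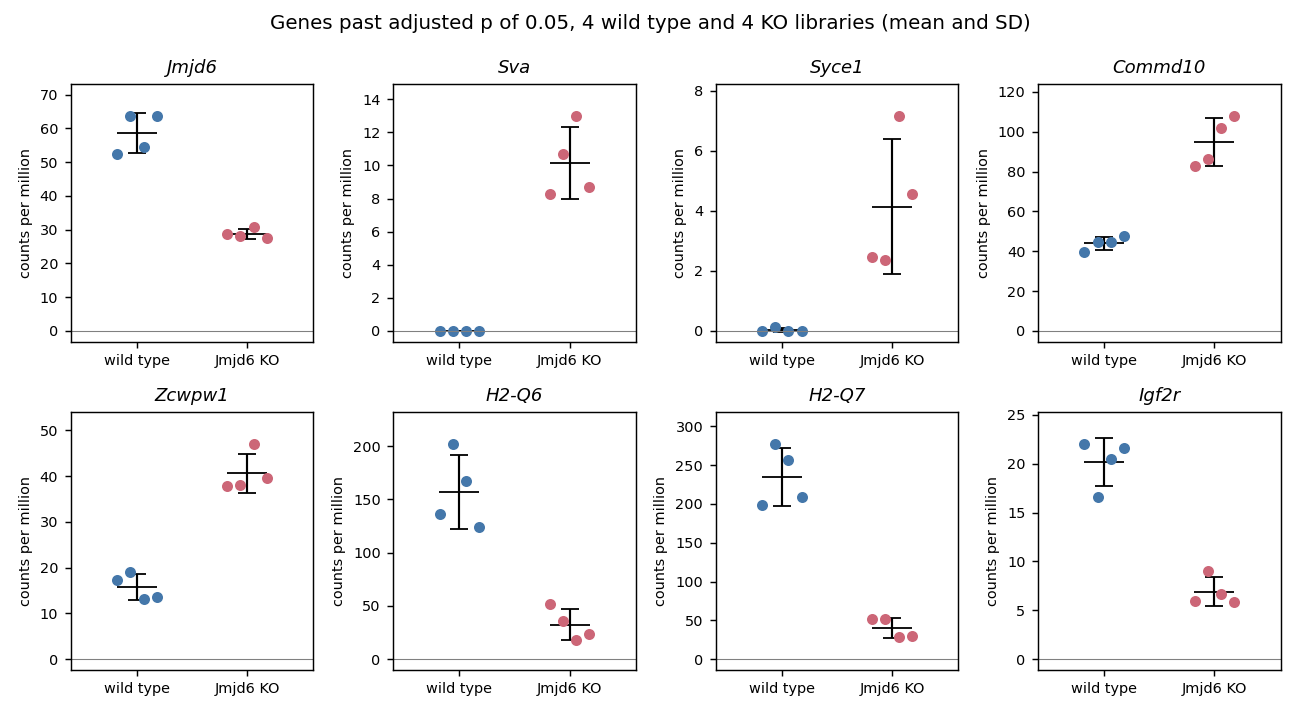
CPM (y axis, from 0) of the 8 genes past an adjusted p of 0.05 in the 4 wild type and 4 Jmjd6 KO libraries; points are libraries, horizontal marks the group means and error bars the SD. Sva lies at 0 in the wild type libraries, and H2-Q7 goes from a mean of 235 to a mean of 40.3.

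Of the 13439 genes, 815 had an unadjusted p under 0.05 where chance alone gives 672, and the groups did not overlap in 4.2% of genes where chance gives 2.86%. With single libraries left out, the genes with an unadjusted p under 0.05 ran from 546 of 13746 to 1035 of 13753. The former was without wild type replicate 3 and the latter without KO replicate 1. Without KO replicate 4 they were 629 of 13587, so the excess over chance was not present in every fit. The count of 8 genes, 4 higher and 4 lower, was 71 by DESeq2, 31 by limma voom with sample weights and 13 with Y-linked expression as a covariate, and all 3 of these fits held the 8. It was between 2 and 8 with single libraries left out, 8 without Jmjd6 KO replicate 3, 7 of them among the reported 8, and 4 among the 6 libraries with Y-linked counts, the last chosen after seeing the data. Against a minimum fold change of 1.2 the calls were 4 genes, Sva, Syce1, H2-Q6 and H2-Q7. Without wild type replicate 1, 2 or 3 or KO replicate 4 the calls were 2 genes, 1 higher and 1 lower, and both were among the 8. Sva and H2-Q7 passed in each of these fits without 1 library, whereas Commd10, Zcwpw1, Igf2r, Syce1 and H2-Q6 kept their direction but lost the call in 5 or more of the 8, with adjusted p by edgeR of up to 0.183.

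The third comparison asked whether groups of genes fixed before the data were examined moved together. Interferon-stimulated genes, the genes that type I interferon induces, fell in KO: 32 of 37 measured members lay below 0, with a median log2 fold change of -0.33 (camera adjusted p = 2.04e-11, and adjusted p = 0.445 with an estimated correlation). Genes of the nuclear-encoded oxidative phosphorylation complexes rose, with all 75 measured members above 0 and a median of 0.28 (camera adjusted p = 4.74e-13, and adjusted p = 0.558 with an estimated correlation). Cytosolic ribosomal protein genes rose likewise, with all 78 above 0 and a median of 0.28 (camera adjusted p = 1.97e-11, and adjusted p = 0.604 with an estimated correlation). Of 34 tested lists, 11 passed with a preset correlation of 0.01, 8 higher and 3 lower, and 0 passed with an estimated correlation, by fry or by permutation of list means. The permutation test could hardly pass any list, since its smallest possible p is 0.0286. Many of the 34 lists would have to reach that value before any passed after adjustment. No list member passed over all genes by edgeR; of 909 members tested, 81 had an unadjusted p under 0.05, 7 passed by DESeq2 and 3 by limma voom.

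Among the interferon-stimulated genes 5 passed by edgeR when adjusted over the list alone and 0 over all genes. Over all genes DESeq2 called Rsad2, Ifit1 and Irf7, at adjusted p of 0.0108, 0.0127 and 0.0367, and limma voom called Ifit1, at 0.0494. Rsad2 (viperin), an antiviral enzyme gene, went from 45.9 ± 2.7 to 26.6 ± 4.41 CPM (log2 fold change -0.79, adjusted over the list alone 0.014 by edgeR). Ifit1, Irf7 and Oas2 gave -0.97, -0.93 and -1.03, and Oasl1 was the other of the 5. The mean log2 CPM of the list was 5.47, 5.40, 5.78 and 5.72 in the wild type libraries and 5.09, 5.28, 5.16 and 5.23 in the KO libraries, without overlap (exact permutation p = 0.0286, adjusted 0.486 over the lists). That p is the smallest the permutation test can give, so its adjusted value could hardly have passed. The camera call held with each library left out in turn, with medians between -0.43 and -0.24. By fry's test for change in either direction the list had an adjusted p of 0.0106, as did the long-term stem cell genes, and the lymphoid priming genes had 0.0317.

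The ribosomal protein and oxidative phosphorylation members were each small in size, and 0 passed by edgeR either over all genes or adjusted over the list alone. Rpl35 gave a log2 fold change of 0.40 (SE 0.15), and Ndufa7, Atp5o and Uqcrh gave 0.53, 0.46 and 0.42. The ribosomal list's mean log2 CPM was 9.36 in KO replicate 4 but 8.34 in KO replicate 3, near the 8.29 of wild type replicate 4. The oxidative phosphorylation mean was 7.49 and 7.46 in KO replicates 3 and 4, and 6.95 and 6.99 in KO replicates 1 and 2, inside the wild type range of 6.81 to 7.11. Their members have short transcripts, with median lengths of 1076.5 and 1141 bases against 3218.5 bases over all tested genes, and log2 fold change across genes correlated with transcript length at a Spearman rho of -0.31, a value across genes, which are not independent replicates. The ribosomal median was 0.17 without wild type replicate 4, 0.43 without KO replicate 3 and 0.13 without KO replicate 4, and that of oxidative phosphorylation 0.18 and 0.19 without KO replicate 3 or 4 and 0.11 by limma voom, with the camera call held each time. Removing a trend of log2 fold change on transcript length and expression level, chosen after seeing the data, took the medians to 0.04 and 0.07.

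Genes of G2 and mitosis rose, with 39 of 40 above 0 and a median of 0.22 (adjusted p = 0.558 with an estimated correlation), among them Prc1 at 0.42 and Cdca8 at 0.46. Genes of S phase and replication rose with a median of 0.18 (adjusted p = 0.445 with an estimated correlation), Fen1 and Gins1 giving 0.45 and 0.50. Ribosome biogenesis genes rose with a median of 0.17, Nip7 and Nop16 giving 0.42 and 0.57 (adjusted p = 0.445 with an estimated correlation). Core spliceosome genes rose with a median of 0.12, Prpf31 and U2af1 giving 0.34 and 0.39 (adjusted p = 0.558 with an estimated correlation). None of the members of these 4 lists passed by edgeR over all genes or adjusted over the list alone. The G2 and mitosis median was 0.35 without wild type replicate 1, and that of ribosome biogenesis 0.11 without KO replicate 3. The core spliceosome median was 0.18 and 0.07 without KO replicate 1 or 4, 0.06 with library size only and 0.07 by limma voom, with the camera call held each time. Removing the trend with length and expression level took the medians of S phase and core spliceosome genes to 0.12 and 0.04. Glycolysis and hypoxia-inducible genes had a median of 0.12, Tpi1 giving 0.29 (camera adjusted p = 0.0428, and adjusted p = 0.558 with an estimated correlation); the call was lost without wild type replicate 1 or 3 or KO replicate 1 or 4, with camera adjusted p of 0.0755, 0.05, 0.0665 and 0.2. The glycolysis call was also lost with library size only, at 0.0515, and by limma voom, at 0.0579, and removing the trend with length and expression level took its median to 0.04.

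Long-term stem cell genes fell with a median of -0.12, 20 of 30 lying below 0 (camera adjusted p = 0.0428, and adjusted p = 0.558 with an estimated correlation). Hlf, a transcription factor gene of stem cells, gave -0.65, Mllt3 -0.45 and Cdkn1c -0.75, while Slamf1 gave 0.93, and 0 members passed by edgeR adjusted over the list alone or over all genes. The call was lost without wild type replicate 2, 3 or 4 or KO replicate 1, 2 or 4, with adjusted p between 0.0679 and 0.216, and the median was -0.19 without wild type replicate 1 and -0.20 with the trend with length and expression level removed. Erythroid genes fell with a median of -0.90 (camera adjusted p = 0.03, and adjusted p = 0.604 with an estimated correlation), Car1 and Tspan33 giving -2.85 and -1.27 with 0 members past edgeR's test either way. Without wild type replicate 1, the library with Car1 at 339 CPM, Car1 gave -0.56 and the erythroid median was 0.01 with a camera adjusted p of 0.945, and the call was also lost without KO replicate 1 or 4, at 0.0679 and 0.0774, with the stricter filter, at 0.0687, and by limma voom, at 0.249. Neutrophil markers rose with a median of 0.60 over 8 members, such as Camp at 1.12 CPM in wild type and 2.77 CPM in KO (camera adjusted p = 0.0039, and adjusted p = 0.558 with an estimated correlation), while S100a8 gave -0.99. The S100a8 value rested on wild type replicate 1, at 84.9 CPM against at most 5.55 CPM in the other wild type libraries, and turned to 1.72 without it. The neutrophil call was lost without wild type replicate 2, with a median of 0.21 and a camera adjusted p of 0.0804, without KO replicate 1, at 0.39 and 0.0679, and with no filter on low counts, at 0.58 and 0.0803. Its median was 1.31 without wild type replicate 1 and 0.22 without KO replicate 3, with the call held.

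**Figure D2:**
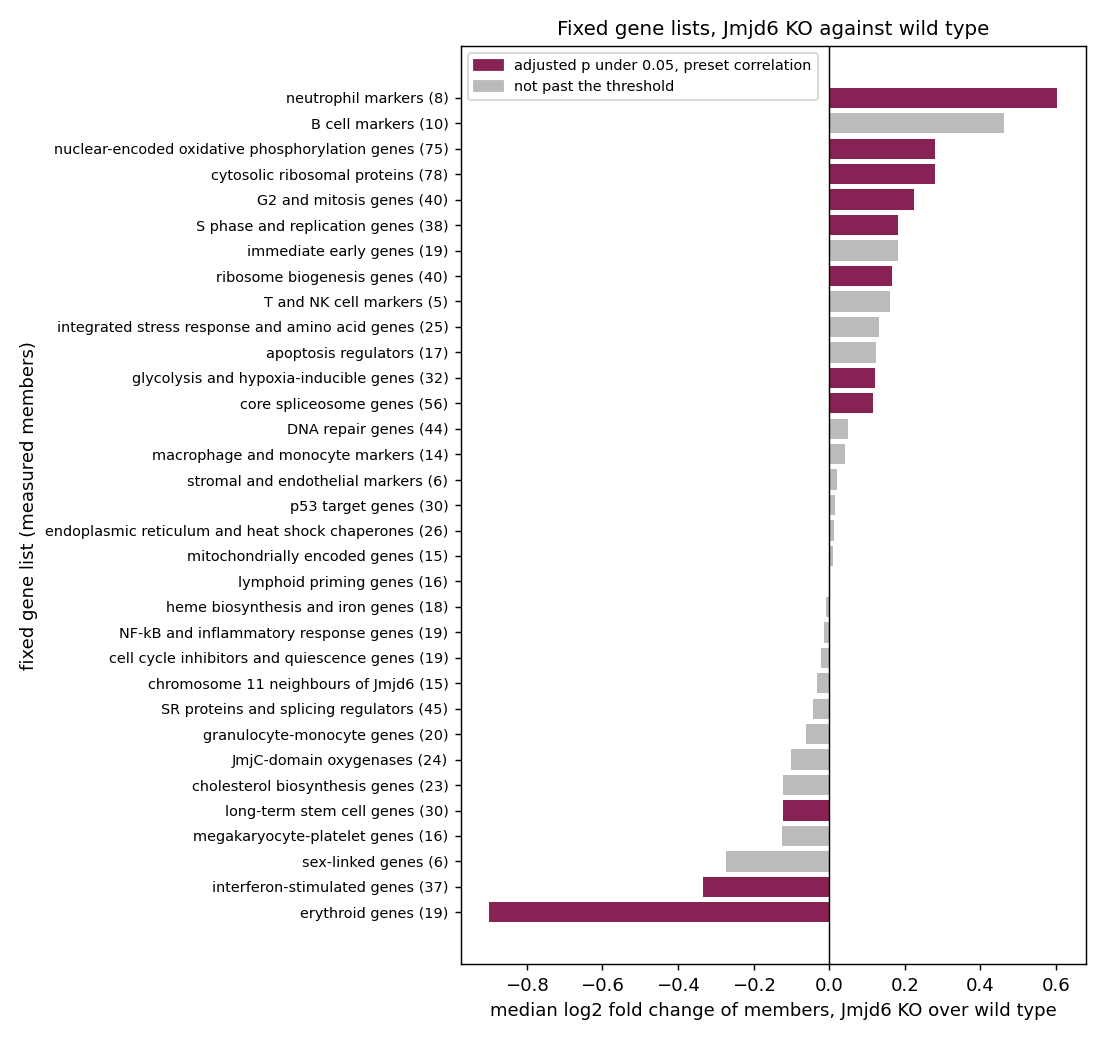
Median log2 fold change, KO over wild type (x axis), of the measured members of the tested lists, 1 left out (y axis, number of members in brackets); dark bars passed an adjusted p of 0.05 with the preset correlation. The interferon-stimulated genes lie at -0.33 and the erythroid genes at -0.90, the latter at 0.01 without wild type replicate 1.

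Lymphoid priming genes had a median of 0.00, a camera adjusted p of 0.237 and 4 members that passed by edgeR adjusted over the list alone, with 0 over all genes. Ly6d and Blnk, which mark and act in B lineage priming, gave log2 fold changes of 1.45 and 0.79, and the chemokine receptor gene Ccr9 gave -1.75, each among the 4. Over all genes DESeq2 gave Ccr9 an adjusted p of 0.0493. Among p53 target genes Cdkn1a, which encodes the cell cycle inhibitor p21, went from 28.1 ± 3.56 to 58.3 ± 12.5 CPM (log2 fold change 1.05, SE 0.192) and was the 1 of 30 to pass adjusted over the list alone, at 0.00465. Over all genes its adjusted p was 0.149 by edgeR, 6e-04 by DESeq2 and 0.016 by limma voom. The other p53 targets did not pass, Btg2 giving 0.46, and the list's median was 0.02 with a camera adjusted p of 0.257. Nkg7 at 0.84 in the granulocyte-monocyte list, Cd4 at 1.05 among T and NK cell markers and Mcpt8 at 1.08 among mast cell, basophil and eosinophil markers each passed by edgeR adjusted over the list alone and not over all genes. DESeq2 called Nkg7 over all genes, at an adjusted p of 0.0493. The last list had 4 measured members, Cpa3 giving 1.31, and was too small for a list test.

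SR proteins and splicing regulators had a median of -0.04 over 45 members (camera adjusted p = 0.669), with Rbfox2 at -0.95, and other JmjC-domain oxygenases -0.10 over 24 members (0.283), with Hspbap1 at 0.58. Neither list passed. Several cell type and stress lists did not pass over all 8 libraries, some of which passed with 1 library left out. B cell markers had a median of 0.46 with Cd79b at 0.53 and Jchain at 1.83 (0.0556), integrated stress response and amino acid genes 0.13 with Pycr1 at 0.82 (0.0808), and apoptosis regulators 0.12 (0.0891). Macrophage and monocyte markers had a median of 0.04 with Lyz2 at 0.38 (0.16), immediate early genes 0.18 (0.236), T and NK cell markers 0.16 (0.237) and DNA repair genes 0.05 (0.251). Cholesterol biosynthesis genes had a median of -0.12 (0.554), heme biosynthesis and iron genes -0.01 with Cpox at -0.74 (0.614), stromal and endothelial markers 0.02 (0.677) and sex-linked genes -0.27 (0.912).

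Among these lists, at the preset correlation, B cell markers passed camera without wild type replicate 2, with a median of 1.16 and an adjusted p of 4.14e-05, and without KO replicate 3, with 0.47 and 0.0101. They also passed with library size only (0.0351), by limma voom (0.0154) and in the 6 libraries with Y-linked counts (0.0209). Over all 8 libraries their adjusted p was 0.577 with an estimated correlation. Macrophage and monocyte markers passed without wild type replicate 4, with a median of 0.35 and an adjusted p of 0.00902, and without KO replicate 4, with 0.27 and 0.0277 (adjusted p = 0.75 with an estimated correlation over all 8). Immediate early genes passed without wild type replicate 2 (0.28, 0.0212) or KO replicate 4 (0.32, 0.00175), by limma voom (0.33, 0.00046) and in the 6 libraries (0.33, 0.0192), against an adjusted p of 0.775 with an estimated correlation over all 8. Integrated stress response genes passed without wild type replicate 4 (0.16, 0.0442) or KO replicate 4 (0.11, 0.0397), by limma voom (0.12, 0.0103) and in the 6 libraries (0.12, 0.045), against an adjusted p of 0.445 with an estimated correlation over all 8. DNA repair genes passed without wild type replicate 1 (0.13, 0.0462), and apoptosis regulators by limma voom (0.16, 0.0257). Over all 8 libraries their adjusted p was 0.75 and 0.445 with an estimated correlation. Over all alternatives the highest adjusted p was 0.624 for B cell markers, 0.833 for macrophage and monocyte markers and 0.955 for immediate early genes.

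In other lists the median, the mean and the test differed in sign. Granulocyte-monocyte genes had a median of -0.06 and a mean of -0.22 with an upward test (0.554), and Elane at -1.76. Without wild type replicate 1 Elane turned to 0.71 and the median of the list was 0.30 with a camera adjusted p of 3.16e-07. Over all 8 libraries the list's adjusted p was 0.936 with an estimated correlation. Mitochondrially encoded genes had a median of 0.01 and a mean of -0.04 with an upward test (0.4). Their median went to -0.34 without wild type replicate 2, at 0.00671, to 0.45 without wild type replicate 1, at 0.00515, to 0.24 without KO replicate 4, at 0.0187, and to 0.42 by limma voom, at 0.0356. These p-values rest on the preset correlation. Over all 8 libraries the correlation between members was estimated at 0.853, and the adjusted p was 0.947 with an estimated correlation. Megakaryocyte-platelet genes had a median of -0.13 and a mean of -0.27 with an upward test (0.912), Selp giving 0.92 and Ppbp -1.91. Endoplasmic reticulum and heat shock chaperones had a median of 0.01 and a mean of -0.03 with an upward test (0.912), and NF-kB and inflammatory response genes -0.01 and 0.02, the test upward (0.912). Cell cycle inhibitors and quiescence genes had a median of -0.02 and a mean of 0.00 with an upward test (0.912).

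**Figure D3:**
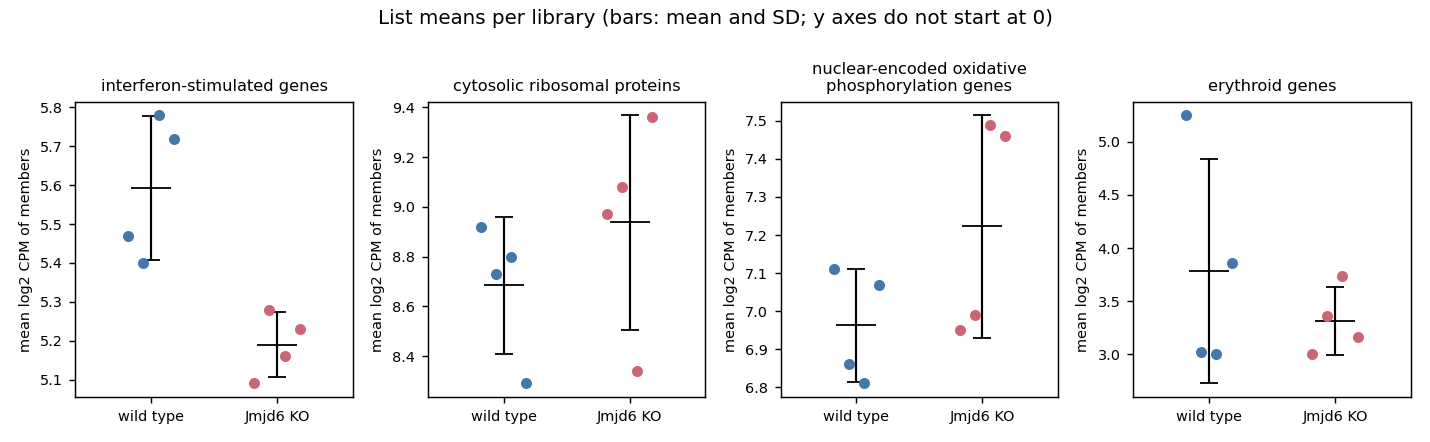
Mean log2 CPM of the members (y axes, not starting at 0) of 4 fixed lists in each wild type and Jmjd6 KO library; points are libraries, horizontal marks the group means and error bars the SD. The interferon-stimulated genes lie at 5.40 or above in wild type and at 5.28 or below in KO, and wild type replicate 1 stands at 5.25 for the erythroid genes.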

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

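The tests of linked blocks, class I reads, sex, single libraries and the length trend were chosen only after the data were seen. The bounds for the counts of splits were written before the splits were counted, but they name the counts of genes and lists that the main tests gave.

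Of 204 tests of 4 libraries each for 1 library far from the other 3, 15 met the limit, and chance gives about 1 in 20 for normally distributed values. Most measures here were CPM values, which need not be normal, and the measures were not independent, so that rate is only a rough guide. Wild type replicate 1 accounted for 7 of them. It held Elane at 785 CPM against at most 56 in the other wild type libraries, Car1 at 339 against at most 41.2, S100a8 at 84.9 against at most 5.55, and Sphk1 at 38.9 against at most 2.26. Its Cpox stood at 34.9 CPM against at most 18.9, its Tspan33 at 8.94 CPM against at most 5.32, and its mean log2 CPM of p53 target genes at 3.99 against at least 4.28. Wild type replicate 4 had Xist at 1630 CPM, ribosomal RNA genes at 0.5% of counts against at least 1.34%, and ribosomal protein genes at 3.09% of counts against at least 4.28%. Both shares were also low in KO replicate 3, at 0.11% and 3.09%, without meeting the limit. The other KO libraries held at least 1.22% and 4.76%. Jmjd6 KO replicate 3 had Xist at 888 CPM and Prc1 at 198 CPM against at most 150. Jmjd6 KO replicate 4 had Ly6d at 15 CPM against at most 6.71 and Tpi1 at 720 CPM against at most 593. The single nonzero wild type library for Syce1 was wild type replicate 2, at 0.133 CPM.

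The 8 called genes, among them Sva, Syce1, H2-Q6 and H2-Q7, were more than any other grouping of the libraries gave. Of 35 splits 1 reached 8, the real one, and the highest of the others called 1 gene. That share is the smallest that 35 splits can give, so it argues against chance for the count but cannot exclude it. The 8 include Jmjd6, the deleted gene, and the other splits place any real difference within their groups, which can lower their counts. Against the sex of the mice as the cause, each genotype held 1 library without Y-linked counts. In addition, 7 of the 7 genes beside Jmjd6 kept their direction with an unadjusted p under 0.001 by edgeR among the 6 libraries with Y-linked counts. Those libraries had also served to select the genes, so these p-values are not independent support. Sva, H2-Q7 and H2-Q6 kept an adjusted p under 0.05 by edgeR there, while Syce1, Commd10, Zcwpw1 and Igf2r lay between 0.064 and 0.142. The 319.5 CPM lost by H2-Q6 and H2-Q7 did not appear as a gain in other class I genes. The other 7 measured H2-K, H2-D and H2-Q genes together stood lower in KO, by -1040 CPM (SE 287). That sum cannot exclude moved reads. H2-K1, at 2330 CPM in wild type and 1690 in KO, and H2-D1, at 1580 and 1250, dominate it, and their falls could hide a gain. Reads left unaligned or uncounted were not seen. Of the 7, only H2-Q2 rose, from 3.11 to 4.96 CPM. Alleles of another mouse strain in blocks that differ between the genotypes stay open and cannot be told apart from an effect of Jmjd6. By edgeR, 12 of 39 genes with p under 0.001 had another such gene 0.5 to 5 Mb away, and 0.0604 of 10000 random draws had as many. Among the 12 were the neighbouring genes H2-Q6, H2-Q7 and H2-Q10, a cluster that random draws of single genes do not allow for. Of the called genes Syce1 was also among the 12, while Jmjd6, Sva, Commd10, Zcwpw1 and Igf2r were not. A biological effect of Jmjd6 loss on these genes also stays open.

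The interferon-stimulated genes, with Rsad2, Ifit1, Irf7 and Oas2 among those lower in KO, did not rest on 1 library: the median log2 fold change nearest 0 with 1 library left out was -0.239. Removing a trend with transcript length and expression level left the median at -0.355 (bootstrap SE 0.068, or 0.174 widened for the correlation between members), which argues against that trend as the whole cause. What stays open is chance, since the list is 1 of the 11 in a count that 12 of 35 splits reached, the correlation between the members, under which its adjusted p was 0.445, and a biological effect of the genotype.

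The ribosomal protein and oxidative phosphorylation genes belong to the same count of lists: 12 of 35 splits gave at least 11 lists, the highest of the others 16, so chance cannot be excluded for that count. The ribosomal median fell from 0.28 to 0.041 once the trend with transcript length and expression level was removed, and the oxidative phosphorylation median from 0.28 to 0.071. The bound written before the trend was removed, more than 2 bootstrap SE above 0, was met by both (SE 0.015 and 0.02), but it took the members as independent, while their estimated correlations were 0.903 and 0.571; SEs widened for these were 0.126 and 0.132, a step chosen after the result was seen, and both medians then lay within 1 SE of 0. With 14.6% and 25.3% of the medians left and the 2 kinds of SE giving different answers, a length trend cannot be told apart from an effect of genotype for either list. The correlation with length was lowest in KO replicates 3 and 4 (-0.22 and -0.39) but 0.21 in KO replicates 1 and 2. In wild type replicates 1 to 4 it was 0.25, -0.02, 0.34 and -0.03, so it varied within each genotype (exact permutation p = 0.371 between genotypes). With 1 library left out the ribosomal and oxidative phosphorylation medians came down to 0.129 and 0.18, between the bounds set for and against a single library.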

How the results depend on the processing

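The 6 libraries with Y-linked counts, the removal of ribosomal RNA genes, permutation of list means, removal of the length trend and, for Jmjd6 itself, a minimum fold change, robust shrinkage, sex-linked genes left out and both covariates were chosen after seeing the data. The count of 8 genes was within 1.5 times under 10 of 24 alternatives. It was 71 by DESeq2, 31 by limma voom, 13 with Y-linked expression as a covariate, 4 with a minimum fold change (Sva, Syce1, H2-Q6 and H2-Q7), 4 in the 6 libraries with Y-linked counts, 2 at an adjusted p of 0.01, and 2 to 8 with single libraries left out; the cause was not tested beyond fewer samples. Jmjd6 kept its direction throughout, between -1.08 and -0.99, and its call was lost with a minimum fold change (-1.03, adjusted p = 0.101), in the 6 libraries (-1.02, adjusted p = 0.105) and in 7 of the 8 fits without 1 library (-1.06 to -0.99); adjusted p ranged from 2.23e-06 to 0.402. The replicate numbers do not pair the samples: correlations of same-numbered libraries were 0.03, -0.01, -0.18 and -0.19, and 0 of 4 wild type libraries correlated best with their own number. Under other numbers, wild type replicate 4 and KO replicate 3, the libraries without Y-linked counts, correlated at 0.42, and wild type replicate 2 and KO replicate 4 at 0.39. The remaining differently numbered pairs lay between -0.29 and 0.26, and a structure shared across genotypes under other numbers was not tested as a block. The fit with Y-linked expression as a covariate, which called 13 genes, sets wild type replicate 4 and KO replicate 3 apart from the rest. It does not cover wild type replicate 2 and KO replicate 4. With the replicate block the count was 3 genes, all among the 8, Jmjd6 stood at -1.02 (adjusted p = 0.402) and 9 lists passed: glycolysis (0.0571), long-term stem cell (0.061) and erythroid genes (0.0916) lost the call and B cell markers (0.0144, but 0.577 with an estimated correlation and no block) gained it. In the 6 libraries long-term stem cell and erythroid genes (0.0539 each) and neutrophil markers (0.0754) lost it. The 11 lists were 0 with an estimated correlation, 0 by fry, 0 by permutation, and 7 to 13 with single libraries left out. The 0 by permutation was close to fixed in advance by the smallest p that test can give, 0.0286. With single libraries left out the erythroid median ran from -1.161 to 0.005, the latter without wild type replicate 1, and that of mitochondrially encoded genes from -0.342, without wild type replicate 2, to 0.449. At this depth and spread, 2-fold changes were recovered in 44.8% of 67 simulated genes, in a draw with 108 calls. With only 8 calls in the data the adjustment is stricter, so recovery there may be lower.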

Other observations

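The genes in this part were chosen after their values were seen. On chromosome 6, Gimap7, Gimap4 and Gimap3, GTPase genes of lymphocyte survival, gave log2 fold changes of 1.23, 1.65 and 1.29 with adjusted p of 0.102, 0.276 and 0.392 by edgeR, so none passed. Every KO library lay above every wild type library for Gimap7, at 25.2 to 40.0 CPM against 10.5 to 15.1 CPM. Their neighbours Gimap6, Gimap5 and Gimap1 gave 0.09, -0.02 and 0.27. Beside H2-Q6 and H2-Q7, the class I genes H2-Q10, H2-K2, H2-K1 and H2-D1 gave log2 fold changes of -1.73, -1.22, -0.47 and -0.34, H2-Q4 and H2-Q1 gave -0.87 and -0.53, and H2-Q2 gave 0.67, at 3.11 CPM in wild type and 4.96 CPM in KO, with adjusted p from 0.276 to 0.909 by edgeR. The antisense gene Airn, which overlaps Igf2r, gave -1.65 and Pilra, which overlaps Zcwpw1, gave 1.2, with adjusted p of 0.772 and 0.429 by edgeR. The unnamed transcript 2410018L13Rik, at -3.42, was the only further gene with an adjusted p under 0.1, at 0.0845 by edgeR.

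Immunoglobulin transcripts varied between libraries of both genotypes. Igkc stood at 0.773, 92.4, 0 and 96 CPM in wild type replicates 1 to 4 and at 19.8, 217, 172 and 157 CPM in the KO libraries. Jchain reached 85.5 CPM in KO replicate 3 and was at 0 in wild type replicate 1. Thbs1 stood at 219 CPM in wild type replicate 4 and at no more than 14.3 CPM in any other library. Gdf3 stood at 93.9 CPM in wild type replicate 4, at 6.93 to 8.72 CPM in the other wild type libraries and at 37.9 to 70.3 CPM in the KO libraries.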
